A study of Mus musculus with 19 samples.

How the data were processed

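RNA sequencing of mouse heart was analysed in 19 samples: wild type with PBS (n = 5), Mcm8 knockout with PBS (n = 3), wild type with LCWE (n = 6) and Mcm8 knockout with LCWE (n = 5). Groups were taken from genotype and treatment in the labels, and replicates were numbered within groups in accession order, which pairs no samples. Per the labels' protocols, RNA was reverse transcribed and preamplified with a whole transcriptome kit before library construction. The deposited values are whole-number gene counts by gene symbol, not normalized, in 1 table of all samples. STAR 2.7.8a, limma 3.36.160 and the mouse genome build GRCm38 are named in the submitters' processing notes without their roles. The counting program, the gene annotation and whether strand was used are not given in the sources used here. Every column of the table matched 1 sample by its label, and 0 columns of other samples were used.

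The table held 25239 symbols, of which 24366 matched GENCODE M21 on GRCm38, used here for coordinates. Total counts per library ranged from 11853233 to 16145911. Counting error alone is small for most named genes, but Mcm8 in the knockout rested on 2 to 13 counts per library and Oas3 in wild-type LCWE on 4 to 15. Mitochondrially encoded genes of the planned list were not in the table, so their share was not computed. Replicate libraries were compared by a chi-square of their counts over 12546 genes. The lowest value per gene was 8.13 within a group and 7.35 between groups, so no pair looked like a duplicate.

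From the deposited counts, genes were kept by filterByExpr of edgeR 4.0.16 in R 4.3.3 (minimum count 10, minimum total 15), which left 14301. Libraries were scaled by TMM and fitted with the robust quasi-likelihood model of edgeR, with all 4 groups in 1 model and no covariates. The contrasts were LCWE against PBS in each genotype, knockout against wild type under each treatment, and the interaction. Adjusted p-values are Benjamini-Hochberg values over the tested genes, with 0.05 as the threshold, and a gene is said to rise, fall or change only where it passed. CPM were computed here from the deposited counts, with TMM factors and a prior count of 2 where on the log2 scale. Gene lists were fixed before the data were examined: 45 lists, of which 44 had at least 3 tested members. They cover leukocyte types, inflammation, interferon and DNA sensing, vessel wall and heart cell types, other tissues, mitochondria and mitophagy, nitric oxide, metabolism, DNA replication, stress, clock, ribosome and sex-linked genes. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and adjusted over the 44 lists. A list call carries the median log2 fold change of its members, with the adjusted p given by an estimated correlation, under which 0 lists were called in each of the 5 contrasts. Counts of members are given over all genes and adjusted over the list alone. Lists not named in the text were not called in any contrast.

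The genes named were chosen by a rule fixed before the data were examined. It takes Mcm8, the 8 called genes with the smallest p in each direction at a mean of at least 5 CPM, or 3 given as values only where fewer than 3 passed, up to 4 members of each called list, and a fixed set given as values (among them Nos2, Nos3, Pink1, Bnip3 and the neighbours of Mcm8). Some genes that this rule picked are left out of the text. Genes named within the range from 100 to under 200, and markers of liver, intestine, skeletal muscle and X inactivation, were chosen after the data were seen.

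The procedure was tested on simulated counts drawn from the real means and library sizes, with 200 of the 14301 genes changed. The changed genes were taken from those with a mean of at least 5 CPM, so recovery of lower genes, such as Mcm8, was not measured. Each gene was drawn independently, without a division of the libraries by sample number. Genes changed 2-fold were recovered in 83.6% for LCWE in wild type, 85.1% for LCWE in the knockout, 77.6% for knockout under PBS and 83.6% for knockout under LCWE. Genes changed 1.5-fold were recovered in 46.3%, 46.3%, 22.4% and 46.3% in the same order, and 4-fold in 97.0%, 100%, 95.5% and 100%. Unchanged genes made up 5.63%, 4.35%, 7.14% and 3.16% of the calls. Comparisons that share the knockout PBS libraries were simulated 20 times without effects.

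Alternatives planned before the data were examined were RLE size factors, library totals alone, no filter or a stricter filter on low counts (5 CPM in 3 libraries), a fit that is not robust, DESeq2 1.42.0, limma-voom with and without library weights, and only the groups compared. Planned covariates were 1 surrogate variable from sva 3.50.0, the Y-linked level, the number of genes detected, and the range of the sample number in the label (under 100, 100 to under 200, 200 and above). Each library was also left out in turn, and lists were tested with an estimated correlation and with fry. Added after the data were seen were covariates for Xist with the Y-linked level and for other tissues, fits of libraries with Xist reads or of 1 number range, and a fit without 2 libraries. Libraries with Xist reads are the 13 with 2351 to 3647 Xist counts, the others holding at most 26, and those with Y-linked reads are the 5 with 1754 to 2164 Y-linked counts, the others holding at most 37. No samples were left out of the analysis over all libraries.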

Results

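Gene counts were analysed for 19 RNA sequencing libraries from mouse heart. They were made to examine the role of the DNA helicase gene Mcm8 in protecting blood vessels in a model of Kawasaki disease. Wild-type hearts gave 5 libraries after PBS and 6 after LCWE, the cell wall extract of Lactobacillus casei that induces vasculitis in this model. Mcm8 knockout hearts gave 3 libraries after PBS and 5 after LCWE. Total counts per library ranged from 11853233 to 16145911. Nothing in the labels says that the samples are separate animals, so the p-values measure the spread between these samples. Folds are on the log2 scale with the standard error of the fit, and levels are means ± SD in CPM, counts scaled to the size of the library.

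Mcm8 itself was measured first, as a check of the genotype labels. It lay at 3.74 ± 0.659 CPM in wild-type PBS hearts (n = 5) and 0.736 ± 0.101 CPM in knockout PBS hearts (n = 3). After LCWE it lay at 4.01 ± 0.961 CPM in wild type (n = 6) and 0.394 ± 0.268 CPM in the knockout (n = 5). The 8 knockout libraries held between 0.136 and 0.827 CPM, and the 11 wild-type libraries between 2.60 and 5.04 CPM. Mcm8 fell in the knockout under PBS (-2.26 ± 0.39, edgeR adjusted p = 0.0316) and under LCWE (-3.36 ± 0.34, adjusted p = 5.12e-05). A two-sided exact permutation test on log2(CPM + 1) gave p = 0.0179 under PBS over 56 splits. Under LCWE it gave an exact p = 0.00216 over 462 splits, and both are the smallest p these designs allow. Under PBS the call on Mcm8 was lost, with folds from -2.41 to -2.17, without any 1 of Wt_PBS replicate 1, 2, 3, 4 or 5, Mcm8Ko_PBS replicate 1 or 3, or Wt_LCWE replicate 5.

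The neighbours of Mcm8 were not called. Mcm8 lies on chromosome 2, 132816141 to 132844197 in GRCm38, next to Trmt6 (chromosome 2, 132804207 to 132816055) and Crls1 (chromosome 2, 132846666 to 132866785). Trmt6, a transfer RNA methyltransferase subunit, differed by 0.24 ± 0.16 under PBS and 0.18 ± 0.13 under LCWE. Crls1, the cardiolipin synthase gene, differed by -0.45 ± 0.19 and -0.13 ± 0.15, with adjusted p from 0.191 upward for both genes. The partner helicase gene Mcm9 differed by -0.25 ± 0.18 and 0.14 ± 0.14 (adjusted p = 0.436 and 0.942).

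**Figure D1:**
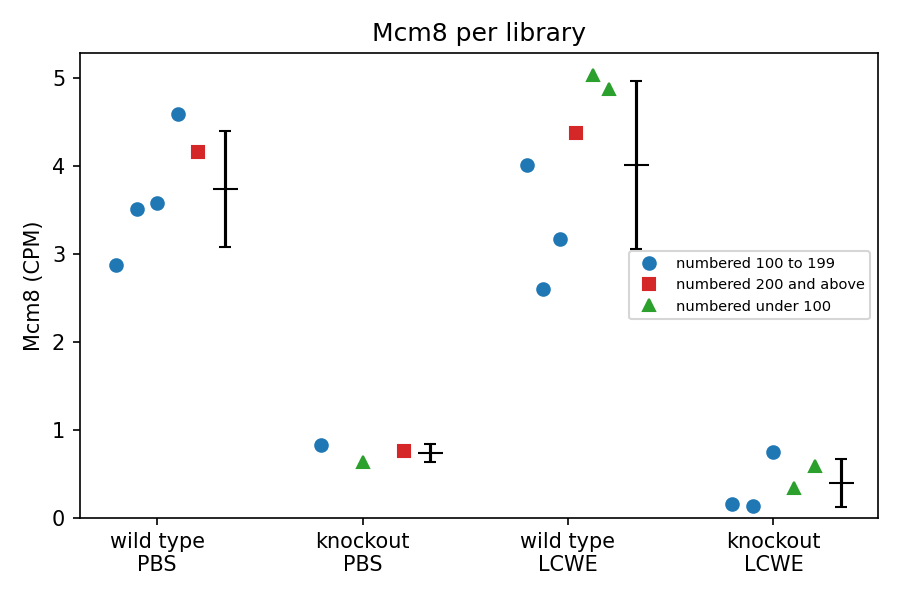
Mcm8 in CPM in each of the 19 libraries, by group, with mean ± SD as black bars and the marker showing the range of the sample number in the label. The 8 knockout libraries lie between 0.136 and 0.827 CPM, below the 11 wild-type libraries at 2.60 to 5.04 CPM.

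The comparison of LCWE with PBS in wild-type hearts asked what the vasculitis model does to the normal heart. Markers of several leukocyte types and of platelets lay higher after LCWE (n = 6) than after PBS (n = 5). These counts do not separate cells in the tissue from blood left in it. The globin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt held 0 counts in every library, so blood content could not be checked with them. T and NK cell markers had a median log2 fold change of 1.94 with 8 of 8 members above 0, among them the T cell kinase gene Lck (2.06 ± 0.58). Camera gave the T and NK cell list an adjusted p = 1.63e-08 (adjusted p = 0.277 with an estimated correlation). Neutrophil markers had a median of 1.49 with 12 of 12 above 0, led by the calprotectin subunit genes S100a8 (2.77 ± 0.95) and S100a9 (2.67 ± 0.98). Camera gave the neutrophil list an adjusted p = 1.50e-05 (adjusted p = 0.417 with an estimated correlation). Monocyte and macrophage markers had a median of 0.69 with 20 of 20 above 0, such as Itgam, which encodes CD11b (0.97 ± 0.36). Camera gave the macrophage list an adjusted p = 5.33e-10 (adjusted p = 0.417 with an estimated correlation). Platelet and erythroid markers had a median of 1.33, with the platelet receptor subunit gene Gp9 at 2.91 ± 0.87. Camera gave the platelet and erythroid list an adjusted p = 5.68e-09 (adjusted p = 0.277 with an estimated correlation). Cytokine genes had a median of 0.50, with the chemokine genes Ccl12 at 2.47 ± 0.64 and Cxcl10 at 1.89 ± 0.55. Camera gave the cytokine list an adjusted p = 3.09e-05 (adjusted p = 0.417 with an estimated correlation).

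Lists of metabolic, antigen presentation and acute phase genes had smaller median log2 fold changes, and the difference from the lists above was not tested. Ribosomal protein genes lay higher in 44 of 44 members, with a median of 0.39. Camera gave the ribosomal protein list an adjusted p = 4.88e-19 (adjusted p = 0.417 with an estimated correlation). Nuclear genes of oxidative phosphorylation lay higher in 51 of 55 members, with a median of 0.26. Camera gave the oxidative phosphorylation list an adjusted p = 5.03e-15 (adjusted p = 0.417 with an estimated correlation). MHC class I genes had a median of 0.39, with H2-K1 at 0.68 ± 0.22. Camera gave the MHC class I list an adjusted p = 5.24e-05 (adjusted p = 0.417 with an estimated correlation). Oxidative stress response genes had a median of 0.17. Camera gave the oxidative stress response list an adjusted p = 0.00965 (adjusted p = 0.417 with an estimated correlation). Complement and acute phase genes had a median of 0.33, with the acute phase gene Saa3 at 1.92 ± 0.85, beside liver transcripts (Alb over 20 CPM) in 4 of 6 LCWE and 2 of 5 PBS libraries. Camera gave the complement list an adjusted p = 0.000556 (adjusted p = 0.417 with an estimated correlation). Lymphocyte progenitor markers (0.36), cell cycle genes (0.40) and MCM and recombination genes (0.13) had positive medians. Camera gave these lists adjusted p = 0.00412, 0.0373 and 0.0410 (0.277, 0.799 and 0.417 with an estimated correlation). The first call was lost without Wt_LCWE replicate 3. The second was lost without Wt_PBS replicate 4 or 5 or Wt_LCWE replicate 1 or 2. The third was lost without Wt_PBS replicate 1, 4 or 5, Mcm8Ko_PBS replicate 3, or Wt_LCWE replicate 1 or 4. Smooth muscle and pericyte markers, such as Myh11 (-0.40 ± 0.20), had a median of -0.11. Camera gave the smooth muscle list an adjusted p = 0.0373 (adjusted p = 0.417 with an estimated correlation), a call lost without Wt_PBS replicate 2, 3 or 5 or Wt_LCWE replicate 4.

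No single gene passed over all libraries in this comparison. Of 14301 genes edgeR called 0, with 892 at an unadjusted p under 0.05 (657 higher, 235 lower), against 1 by DESeq2, 0 by limma-voom and 1 with library weights. Adjusted over the list alone, 6 of 8 T and NK cell markers, 3 of 13 platelet and erythroid markers, 3 of 21 cytokine genes and 2 of 8 lymphocyte progenitor markers rose. The other 10 called lists had 0 such members. The smallest p-values among lower genes belonged to Ddit4, a stress-induced inhibitor of mTOR signalling (-1.23 ± 0.26), Irf2bp2 (-0.52 ± 0.12) and Bcl7a (-0.32 ± 0.08). Among higher genes they belonged to Lsm8 (0.43 ± 0.12), Hes6 (0.47 ± 0.13) and the cathepsin gene Ctso (0.35 ± 0.10), all with adjusted p = 0.772. With the sample-number range as a covariate 9 lists were called. The lists for MHC class I (adjusted p = 0.0896), complement (0.0739), oxidative stress (0.0515), MCM (0.112) and smooth muscle (0.230) were then not called.

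The labels carry sample numbers whose meaning is not given. Of the wild-type libraries, 4 after PBS and 3 after LCWE are numbered 100 to under 200, and the comparison was repeated within that range, a restriction chosen after the data were seen. There LCWE raised the complement gene C1qb, made by tissue macrophages, from 47.8 ± 4.49 CPM (n = 4) to 104 ± 11.5 CPM (n = 3). Its change was 1.16 ± 0.12 (edgeR adjusted p = 0.00407), against 0.82 over all libraries. C1qa (1.06 ± 0.13), C1qc (1.10 ± 0.15) and the leukotriene synthesis gene Alox5ap (1.07 ± 0.12) rose with it. Parm1 (-0.94 ± 0.14) and the ephrin receptor gene Epha4 (-1.32 ± 0.20) fell. Of 20 macrophage markers 14 rose over all genes and 15 adjusted over the list alone (camera adjusted p = 5.13e-13, and adjusted p = 0.134 with an estimated correlation). Of 12 neutrophil markers 4 rose, such as S100a8 (3.30 ± 0.55), and 7 adjusted over the list alone (camera adjusted p = 4.42e-05, and adjusted p = 0.392 with an estimated correlation). Of 8 T and NK cell markers 4 rose, such as Cd8a (2.91 ± 0.60), and 5 adjusted over the list alone (camera adjusted p = 8.64e-05, and adjusted p = 0.392 with an estimated correlation). Of 21 cytokine genes 4 rose, among them Cxcl10 (2.23 ± 0.60) and Ccl5 (1.97 ± 0.49), and 5 adjusted over the list alone (camera adjusted p = 0.000818, and adjusted p = 0.185 with an estimated correlation). Ribosomal protein genes rose in 37 of 44 members and in 42 adjusted over the list alone (camera adjusted p = 3.96e-20, and adjusted p = 0.437 with an estimated correlation). Rn45s, the gene of the 45S ribosomal RNA precursor, rose by 1.53 ± 0.20, from 633 ± 105 CPM to 1796 ± 572 CPM. Over all libraries it differed by 0.96 and was not called. Whether these rises came from the tissue or from library preparation was not tested. Oxidative phosphorylation genes rose in 28 of 55 and in 39 adjusted over the list alone (camera adjusted p = 1.69e-14, and adjusted p = 0.444 with an estimated correlation). In all, 1247 genes changed (777 higher, 470 lower). The count was 319, 155, 715 and 460 without Wt_PBS replicate 1, 2, 3 and 4, and 3162, 6 and 89 without Wt_LCWE replicate 1, 2 and 3. It was 492 without the 4 knockout libraries of that range, which were in the fit. From 200 upward, with 1 library in each group, the macrophage markers differed by a median of 0.21, against 0.99 in the range 100 to under 200. No wild-type PBS library is numbered under 100.

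The comparison of LCWE with PBS in Mcm8 knockout hearts asked how hearts without Mcm8 respond to the model. Here 415 genes changed (n = 5 and 3), of which 298 fell. Ptprc, which encodes the pan-leukocyte phosphatase CD45, rose (1.37 ± 0.27, edgeR adjusted p = 0.0261). Mrc1, the macrophage mannose receptor gene, rose from 14.1 ± 5.76 CPM (n = 3) to 37.3 ± 8.70 CPM (n = 5), a change of 1.36 ± 0.25. Macrophage markers had a median of 1.41 with 20 of 20 above 0, 3 called over all genes (Mrc1, Itgam and Tyrobp) and 16 adjusted over the list alone. Camera gave the macrophage list an adjusted p = 1.87e-09 (adjusted p = 0.485 with an estimated correlation). Fatty acid oxidation genes fell, 12 of 33 over all genes and 24 adjusted over the list alone, with a median of -0.58. Among them were the electron transfer gene Etfdh (-0.80 ± 0.17), the carnitine carrier gene Slc25a20 (-0.64 ± 0.15) and the dehydrogenase gene Acadm (-0.60 ± 0.14). Camera gave the fatty acid oxidation list an adjusted p = 1.74e-13 (adjusted p = 0.485 with an estimated correlation). This list was not called among libraries with Xist reads (camera adjusted p = 0.102) or, with 1 PBS library, under 100 (0.116). Heat shock genes fell, 4 of 18 over all genes and 9 adjusted over the list alone, with a median of -0.52. They were led by the Hsp70 genes Hspa1b (-2.71 ± 0.57) and Hspa1a (-2.12 ± 0.49), a near-identical pair between which reads can be shared. Camera gave the heat shock list an adjusted p = 0.000236 (adjusted p = 0.485 with an estimated correlation).

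Vessel, clock and stress genes changed in the same comparison. Endothelial markers fell, 4 of 26 over all genes and 6 adjusted over the list alone, with a median of -0.21. The called members were the arterial transcription factor gene Sox17 (-0.91 ± 0.22), the venous factor gene Nr2f2 (-0.76 ± 0.18), Efnb2 (-0.67) and the fatty acid transporter gene Cd36 (-0.84). Camera gave the endothelial list an adjusted p = 0.00203 (adjusted p = 0.485 with an estimated correlation). Clock genes fell, 2 of 19 over all genes (Cry1 among them) and 5 adjusted over the list alone, with a median of -0.77. Camera gave the clock list an adjusted p = 0.000361 (adjusted p = 0.485 with an estimated correlation). The clock list was not called without Mcm8Ko_PBS replicate 1 and Mcm8Ko_LCWE replicate 2 (camera adjusted p = 0.0987), among libraries with Xist reads (0.102) or under 100 (0.683, higher). Unfolded protein and integrated stress response genes fell, 3 of 26 over all genes (Ddit4, Dnajc3 and Herpud1) and 8 adjusted over the list alone, with a median of -0.46. Camera gave the unfolded protein response list an adjusted p = 0.00620 (adjusted p = 0.485 with an estimated correlation), a call lost without Mcm8Ko_PBS replicate 3. Extracellular matrix genes had a median of 0.73, and Dpt, the dermatopontin gene, rose over all genes and adjusted over the list alone (0.99 ± 0.26). Camera gave the extracellular matrix list an adjusted p = 0.0107 (adjusted p = 0.586 with an estimated correlation), a call lost without Mcm8Ko_PBS replicate 3 or Mcm8Ko_LCWE replicate 1 or 2. Within the libraries numbered under 100, with 1 PBS library, this list was lower instead (camera adjusted p = 0.0471). Neutrophil markers, with S100a8 at 3.74 ± 1.22, had a median of 2.18, with 0 of 12 called over all genes and 8 adjusted over the list alone. Camera gave the neutrophil list an adjusted p = 0.00500 (adjusted p = 0.490 with an estimated correlation), a call lost without Mcm8Ko_LCWE replicate 4. T and NK cell markers (1.85), cell cycle genes (0.71), cytokine genes (0.71) and ribosomal protein genes (0.21) had positive medians, with 0 members called over all genes or adjusted over the list alone. Camera gave these lists in turn adjusted p = 0.000361, 0.000236, 0.00503 and 0.00620. With an estimated correlation they were 0.485, 0.554, 0.486 and 0.838. The cytokine call was lost without Mcm8Ko_PBS replicate 1 or Mcm8Ko_LCWE replicate 4. The ribosomal protein call was lost without Mcm8Ko_PBS replicate 2 or 3 or Mcm8Ko_LCWE replicate 4. Inflammasome genes (median 0.49) and MCM and recombination genes (median 0.24) each had 1 gene called over all genes and adjusted over the list alone, the adaptor gene Pycard (1.35 ± 0.32) and the helicase subunit gene Mcm3 (0.74 ± 0.19). Camera gave these lists adjusted p = 0.00911 and 0.00770 (0.490 and 0.485 with an estimated correlation). The first call was lost without Mcm8Ko_PBS replicate 1 or Mcm8Ko_LCWE replicate 4, and the second without Mcm8Ko_PBS replicate 3. Calls on the extracellular matrix (adjusted p = 0.0625) and ribosomal protein lists (0.0518) were lost with the sample-number range as a covariate.

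The genes with the smallest p that fell after LCWE in the knockout were led by the cytochrome P450 gene Cyp4b1 (-1.27 ± 0.16, edgeR adjusted p = 0.00203). After it came Als2cl (-0.89), Tmcc3 (-0.99), Ggnbp1 (-0.69), Dock9 (-0.76), Rasgrp2 (-1.10), Rhpn2 and the collagen gene Col11a2 (-1.58). Beside Mrc1 and Ptprc, those that rose were Olfml3 (1.04), the histone variant gene Macroh2a2 (0.98), the tubulin gene Tuba4a (1.38), Haghl (0.69), Gas7 (1.06) and the small GTPase gene Rrad (1.31). The count of 415 became 1 without Mcm8Ko_PBS replicate 1, 19 without Mcm8Ko_LCWE replicate 5, 32 without Mcm8Ko_LCWE replicate 3, 34 without Mcm8Ko_LCWE replicate 1, 57 without Mcm8Ko_PBS replicate 3, 210 without Wt_PBS replicate 1, 214 without Wt_PBS replicate 3, 224 without Wt_PBS replicate 2, 246 without Wt_LCWE replicate 1, and 256 without Wt_PBS replicate 4. It became 741 without Wt_LCWE replicate 3 and 2935 without Mcm8Ko_PBS replicate 2. Each number range held 1 knockout PBS library, so a fit within a range assumes that this library varies like the others. Such fits called 3941 genes among libraries numbered 100 to under 200 and 3 under 100, and the range as a covariate left 116.

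The comparison of knockout with wild type under PBS asked what loss of Mcm8 does to the unchallenged heart. Here 86 genes changed (n = 3 and 5), 75 higher and 11 lower. The Hsp70 genes Hspa1b (3.12 ± 0.58) and Hspa1a (2.55 ± 0.50), a near-identical pair, rose (edgeR adjusted p = 0.0316 and 0.0342). Ddit3, which encodes the stress transcription factor CHOP, rose by 1.65 ± 0.33 (adjusted p = 0.0352). The clock gene Per2 rose from 10.2 ± 3.63 CPM (n = 5) to 80.0 ± 47.7 CPM (n = 3), a change of 3.06 ± 0.64. Clock genes had a median of 1.06, with 2 of 19 higher over all genes (Per2 among them), and 12 higher and 1 lower adjusted over the list alone. Camera gave the clock list an adjusted p = 5.02e-05 (adjusted p = 0.577 with an estimated correlation). Interferon-stimulated genes lay above wild type in 37 of 37 members, with a median of 0.86. Their mean was 4.06 and 4.78 log2 CPM in Mcm8Ko_PBS replicates 1 and 2, above every wild-type PBS library, and 3.26 in replicate 3, below all of them but Wt_PBS replicate 4 (2.33). Of these genes Herc6, an interferon-induced ligase family gene (4.80 ± 0.659 CPM, n = 5, and 9.23 ± 2.37 CPM, n = 3), rose over all genes and 15 rose adjusted over the list alone. Camera gave the interferon-stimulated gene list an adjusted p = 3.87e-09 (adjusted p = 0.577 with an estimated correlation). Fatty acid oxidation genes had a median of 0.51, with 0 of 33 called over all genes and 17 higher adjusted over the list alone. Camera gave the fatty acid oxidation list an adjusted p = 5.23e-08 (adjusted p = 0.577 with an estimated correlation).

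Further lists were higher in knockout PBS hearts. Unfolded protein and integrated stress response genes had a median of 0.57, with 2 of 26 called over all genes (Ddit3 and Dnajc3) and 9 adjusted over the list alone. Camera gave the unfolded protein response list an adjusted p = 0.00599 (adjusted p = 0.577 with an estimated correlation), a call lost without Mcm8Ko_PBS replicate 3. The heat shock list had a median of 0.28, with 2 of 18 called over all genes and 6 adjusted over the list alone. Camera gave the heat shock list an adjusted p = 0.00831 (adjusted p = 0.577 with an estimated correlation), a call lost without Mcm8Ko_PBS replicate 3. MHC class I genes had a median of 0.57, with H2-Q4 (1.16 ± 0.26) called over all genes and 7 members adjusted over the list alone, and reads can be shared between these near-identical genes. Camera gave the MHC class I list an adjusted p = 0.00406 (adjusted p = 0.580 with an estimated correlation), a call lost without Mcm8Ko_PBS replicate 2. Oxidative stress response genes had a median of 0.22, with 0 called over all genes and 8 adjusted over the list alone, and the heme oxygenase gene Hmox1 at 1.71 ± 0.40 (adjusted p = 0.0554). Camera gave the oxidative stress response list an adjusted p = 0.00654 (adjusted p = 0.577 with an estimated correlation). Endothelial markers had a median of 0.22, with Sox17 (1.02 ± 0.22) called over all genes and 2 adjusted over the list alone. Camera gave the endothelial list an adjusted p = 0.00406 (adjusted p = 0.577 with an estimated correlation). Complement genes had a median of 0.34, with Steap4 (0.70 ± 0.16) called over all genes and 3 adjusted over the list alone, beside Alb over 20 CPM in 2 of 3 knockout and 2 of 5 wild-type libraries. Camera gave the complement list an adjusted p = 0.00599 (adjusted p = 0.577 with an estimated correlation). DNA sensing genes (0.32) and platelet and erythroid markers (0.70) had positive medians with 0 members called over all genes or adjusted over the list alone. Camera gave these lists adjusted p = 0.0333 and 0.0150 (0.577 and 0.580 with an estimated correlation). Both calls were lost without Wt_PBS replicate 3, the first also without Mcm8Ko_PBS replicate 2 and the second without Mcm8Ko_PBS replicate 3. MHC class II and dendritic cell genes (-0.57) and MCM and recombination genes (-0.20) had negative medians, and beside Mcm8 no member of them was called over all genes. Adjusted over the list alone, 2 MCM and recombination genes were higher and 1 was lower, and 0 MHC class II genes. Camera gave both lists an adjusted p = 0.0398 (0.577 with an estimated correlation). The MHC class II call was lost without Wt_PBS replicate 1 or 5, Mcm8Ko_PBS replicate 1 or 3, or Wt_LCWE replicate 3. The MCM and recombination call was lost without Wt_PBS replicate 2, 3 or 5 or Mcm8Ko_PBS replicate 3. This list holds the deleted gene Mcm8 itself, so its call does not stand for the other members alone. With the sample-number range as a covariate the MHC class I (adjusted p = 0.0615), DNA sensing (0.151), complement (0.151) and MCM lists (0.0786) were not called.

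The other genes with the smallest p that rose in knockout PBS hearts were the stress-response gene Osgin1 (1.49), Cyp4b1 (0.90), Pde2a, a phosphodiesterase that cGMP stimulates (0.78), and Als2cl (0.76). Fnbp1l (0.87), Il17rd (0.72), Fam124a (1.10) and the glycerol phosphate dehydrogenase gene Gpd1 (1.41) followed. Beside Mcm8, those that fell were Hacd2 (-0.66), Wdr6 (-0.64), Macroh2a2 (-0.86), Abhd14a (-0.67) and Zfp267 (-0.88). The count of 86 became 0 without Wt_PBS replicate 1, 2 or 3, Mcm8Ko_PBS replicate 1 or 3, or Wt_LCWE replicate 5, 1 without Wt_PBS replicate 4, 5 without Wt_PBS replicate 5, 27 without Wt_LCWE replicate 4, 33 without Wt_LCWE replicate 6, 35 without Mcm8Ko_LCWE replicate 1, 37 without Wt_LCWE replicate 1, and 48 without Mcm8Ko_LCWE replicate 3. It became 2606 without Mcm8Ko_PBS replicate 2. The range 100 to under 200 held 1 knockout PBS library, and with it assumed to vary like the others 3936 genes were called, while the range as a covariate gave 524.

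The comparison of knockout with wild type after LCWE asked whether loss of Mcm8 alters the inflamed heart. Interferon-stimulated genes lay higher in the knockout (n = 5) than in wild type (n = 6) in 37 of 37 members, with a median of 0.95. The antiviral synthase gene Oas3 lay at 0.558 ± 0.266 CPM in wild type and 5.89 ± 5.30 CPM in the knockout (3.33 ± 0.69), and the interferon signalling genes Stat2 and Irf9 differed by 1.09 ± 0.24 and 0.95 ± 0.21. Over all genes 0 members were called, the smallest adjusted p being 0.501, and 32 rose adjusted over the list alone. Camera gave the interferon-stimulated gene list an adjusted p = 6.40e-33 (adjusted p = 0.392 with an estimated correlation). The mean log2 level of the list exceeded every wild-type LCWE library in 3 of the 5 knockout LCWE libraries. Isg15 and Ifit3 differed by 1.12 ± 0.46 and 1.77 ± 0.54 (edgeR adjusted p = 0.853 and 0.804). Nuclear oxidative phosphorylation genes lay lower in 55 of 55 members, with a median of -0.27 and Cox7a1, a heart and muscle subunit gene of cytochrome oxidase, at -0.56 ± 0.15. None of them was called over all genes or adjusted over the list alone. Camera gave the oxidative phosphorylation list an adjusted p = 1.30e-25 (adjusted p = 0.452 with an estimated correlation). Mean log2 CPM was 9.37 ± 0.11 in knockout LCWE, near wild-type PBS (9.41 ± 0.08), and 9.62 ± 0.24 in wild-type LCWE. In wild type the LCWE difference was 0.46 within 100 to under 200 and -0.10 from 200 upward (1 library each). Within the libraries numbered 100 to under 200 (3 of each genotype) the median difference over members was 0.55 for the interferon list and -0.39 for oxidative phosphorylation. Within those under 100 (2 of each) it was 1.30 and -0.17. In the range 100 to under 200 the interferon list lay at 5.25, 3.72 and 3.43 log2 CPM in Mcm8Ko_LCWE replicates 1, 2 and 3, against 3.42, 3.89 and 3.40 in Wt_LCWE replicates 1, 2 and 3, so the difference there rested on Mcm8Ko_LCWE replicate 1.

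**Figure D2:**
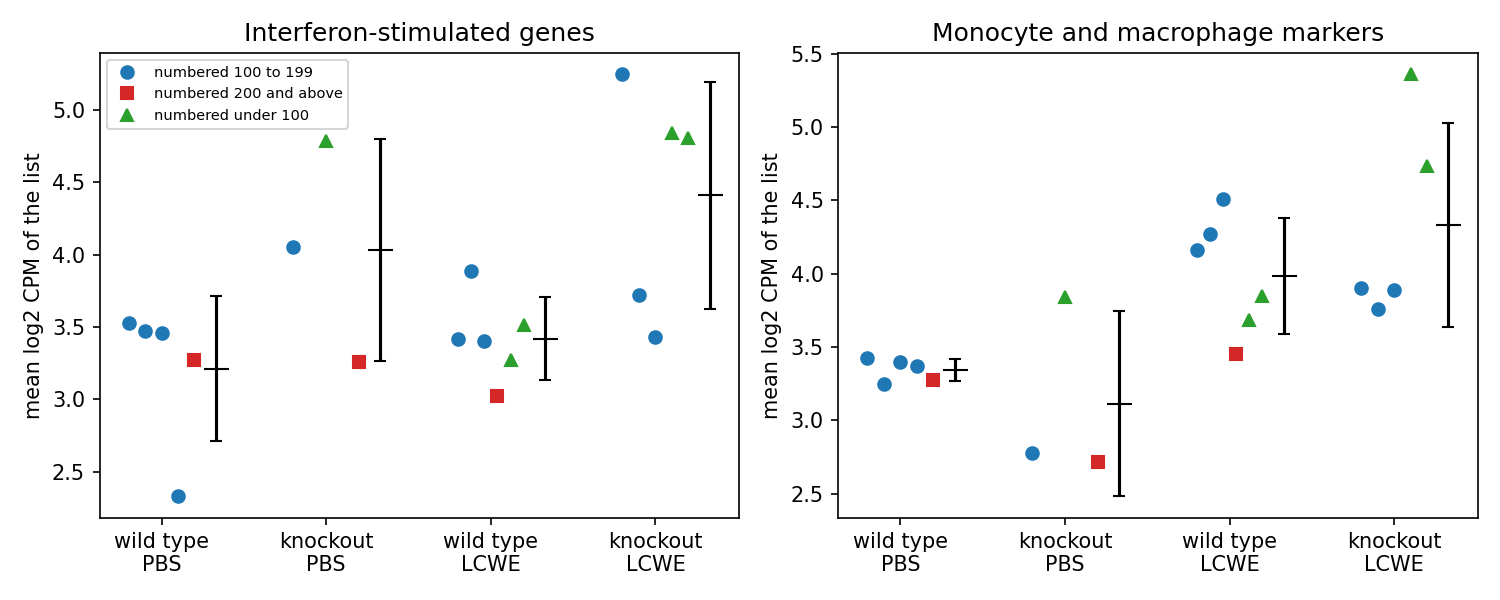
Mean log2 CPM of the interferon-stimulated genes (left) and of the monocyte and macrophage markers (right) in each library, by group, with mean ± SD as black bars and the marker showing the range of the sample number. The interferon list lies between 3.43 and 5.25 in the 5 knockout LCWE libraries and between 3.03 and 3.89 in the 6 wild-type LCWE libraries.

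Macrophage markers did not keep their direction between the number ranges after LCWE. Over all libraries they had a median of 0.37, with Ly6c2, a marker of inflammatory monocytes, at 1.67 ± 0.51. Camera gave the macrophage list an adjusted p = 0.00246 (adjusted p = 0.668 with an estimated correlation), a call lost without Wt_LCWE replicate 4 or Mcm8Ko_LCWE replicate 4. Within libraries numbered 100 to under 200 they were lower in the knockout, with a median difference of -0.52 (camera adjusted p = 5.49e-08). Under 100 they were higher, with a median difference of 1.33 (camera adjusted p = 7.82e-16). Ribosomal protein genes had a median of -0.16 over all libraries, and differed by -0.49 and 0.31 in the 2 ranges. Camera gave the ribosomal protein list an adjusted p = 0.0116 (adjusted p = 0.741 with an estimated correlation), a call lost without Wt_LCWE replicate 2 or 3 or Mcm8Ko_LCWE replicate 1 or 2. DNA sensing genes had a median of 0.42, with 5 members higher adjusted over the list alone, 0 over all genes, and the nucleic acid sensor gene Zbp1 at 2.04 ± 0.61. Camera gave the DNA sensing list an adjusted p = 0.00246 (adjusted p = 0.566 with an estimated correlation), a call lost without Mcm8Ko_LCWE replicate 4. MHC class I genes had a median of 0.26 with 14 of 14 above 0. Camera gave the MHC class I list an adjusted p = 0.000360 (adjusted p = 0.566 with an estimated correlation). Within 100 to under 200 they were lower and not called (camera adjusted p = 0.605), and under 100 higher (camera adjusted p = 5.88e-10). Complement genes had a median of 0.32 with 22 of 22 above 0 and Saa3 at 1.88 ± 0.71, beside Alb over 20 CPM in 5 of 5 knockout and 4 of 6 wild-type libraries. Camera gave the complement list an adjusted p = 0.00226 (adjusted p = 0.566 with an estimated correlation), a call lost without Mcm8Ko_LCWE replicate 4. Immediate early genes had a median of 0.29. Camera gave the immediate early list an adjusted p = 0.00701 (adjusted p = 0.566 with an estimated correlation), a call lost without Wt_LCWE replicate 3 or 6 or Mcm8Ko_LCWE replicate 1 or 2. Lists with negative medians were fatty acid oxidation (-0.14), mitochondrial DNA maintenance and biogenesis (-0.11), platelet and erythroid markers (-0.40) and contractile genes (-0.11, mean -0.02), such as the myoglobin gene Mb (-0.37 ± 0.11). Camera gave the fatty acid oxidation list an adjusted p = 5.00e-05 (adjusted p = 0.566 with an estimated correlation), a call lost without Mcm8Ko_LCWE replicate 2. Among libraries with Xist reads, 1 of them knockout LCWE, the fatty acid oxidation list was higher in the knockout instead (camera adjusted p = 0.00758), and so was the ribosomal protein list (camera adjusted p = 0.0332). Camera gave the mitochondrial DNA and platelet and erythroid lists adjusted p = 0.00327 and 0.00226 (0.392 and 0.566 with an estimated correlation). The platelet and erythroid call was lost without Wt_LCWE replicate 3. This list was lower within 100 to under 200 (camera adjusted p = 2.19e-06), and higher and not called under 100 (camera adjusted p = 0.499). Camera gave the contractile list an adjusted p = 0.0178 (adjusted p = 0.463 with an estimated correlation), a call lost without Wt_LCWE replicate 6 or Mcm8Ko_LCWE replicate 2 or 4. Apart from the interferon and DNA sensing lists, 0 members of these lists were called, over all genes or adjusted over the list alone.

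Mcm8 was the only gene of 14301 that edgeR called between genotypes after LCWE, with 794 at an unadjusted p under 0.05. DESeq2 called 6, limma-voom 1 and limma-voom with library weights 2, and edgeR 2 without Mcm8Ko_LCWE replicate 3. The smallest p-values among other lower genes belonged to the heme synthesis gene Uros (-0.40 ± 0.09), Fahd1 (-0.49 ± 0.12) and Cmtm8 (-0.48 ± 0.12). Within ranges edgeR called 0 genes from 100 to under 200, with 1960 at an unadjusted p under 0.05, and 128 under 100, and the number range as a covariate left 1.

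The difference between the LCWE responses of the genotypes was tested as an interaction. Lists of lipid metabolism, stress and clock genes lay lower in the knockout response. Heat shock genes had mean log2 CPM of 6.80 (PBS) and 6.75 (LCWE) in wild type, and 7.21 and 6.69 in the knockout. For clock genes it was 4.59 and 4.66, and 5.44 and 4.78, so both differences lay mostly in the 3 knockout PBS libraries. Fatty acid oxidation genes (8.45, 8.40, 8.89 and 8.21) also lay lower in the knockout after LCWE. Fatty acid oxidation genes responded by -0.58 in the knockout and 0.00 in wild type, and the median difference was -0.61 with 31 of 33 members below 0. Of them 0 were called over all genes and 16 were lower adjusted over the list alone, with the carrier gene Slc25a20 at -0.73 ± 0.20. Camera gave the fatty acid oxidation list an adjusted p = 4.33e-16 (adjusted p = 0.413 with an estimated correlation). Heat shock genes differed by a median of -0.37, with 3 of 18 lower adjusted over the list alone and Hspa1b at -2.76 ± 0.78. Camera gave the heat shock list an adjusted p = 0.000136 (adjusted p = 0.478 with an estimated correlation), a call lost without Mcm8Ko_PBS replicate 3. Clock genes differed by -0.92, with 1 of 19 lower adjusted over the list alone and Per2 at -2.21 ± 0.84. Camera gave the clock list an adjusted p = 0.000351 (adjusted p = 0.413 with an estimated correlation). Its call was lost without Mcm8Ko_PBS replicate 1 and Mcm8Ko_LCWE replicate 2 (camera adjusted p = 0.149) and among libraries with Xist reads (0.118). Oxidative stress genes differed by -0.30, with 2 of 28 lower adjusted over the list alone. Camera gave the oxidative stress response list an adjusted p = 0.000311 (adjusted p = 0.413 with an estimated correlation). Macrophage markers (0.65) and extracellular matrix genes (0.63) differed toward a larger response in the knockout. Camera gave these lists adjusted p = 0.000779 and 0.00532 (0.751 for both with an estimated correlation). Both calls were lost without Mcm8Ko_PBS replicate 3, the first also without Mcm8Ko_LCWE replicate 4 and the second without Mcm8Ko_LCWE replicate 2. Platelet and erythroid markers (-1.54) and endothelial markers (-0.27) differed in the other direction. Camera gave these lists adjusted p = 1.54e-05 and 0.00273 (0.413 and 0.583 with an estimated correlation). The other called lists were the nuclear oxidative phosphorylation (-0.17), mitochondrial DNA maintenance (-0.16), autophagy and lysosome (-0.0525), cell cycle (0.30) and Schwann and neuronal lists (0.45). Camera gave the oxidative phosphorylation list an adjusted p = 0.000341 (adjusted p = 0.796 with an estimated correlation). Camera gave the mitochondrial DNA list an adjusted p = 0.0388 (adjusted p = 0.420 with an estimated correlation), a call lost without Wt_PBS replicate 1 or 2, Mcm8Ko_PBS replicate 1 or 3, Wt_LCWE replicate 4, 5 or 6, or Mcm8Ko_LCWE replicate 1, 2 or 4. Camera gave the autophagy list an adjusted p = 0.0467 (adjusted p = 0.751 with an estimated correlation), a call lost without Wt_PBS replicate 1, 4 or 5, Mcm8Ko_PBS replicate 1, Wt_LCWE replicate 1, 4, 5 or 6, or Mcm8Ko_LCWE replicate 2 or 5. Camera gave the cell cycle and Schwann and neuronal lists adjusted p = 0.00532 and 0.0266 (0.763 and 0.413 with an estimated correlation). Both calls were lost without Mcm8Ko_PBS replicate 3, and the second also without Wt_PBS replicate 5 or Mcm8Ko_LCWE replicate 2 or 4. The extracellular matrix (adjusted p = 0.536), cell cycle (0.197), mitochondrial DNA (0.197) and autophagy lists (0.105) lost their calls with the sample-number range as a covariate.

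Of single genes, edgeR called 0 in the interaction, with 1145 at an unadjusted p under 0.05, against 3 by DESeq2, 0 by limma-voom and 21 with library weights. The smallest p belonged to Cyp4b1, which fell by 1.27 after LCWE in the knockout and differed by -1.26 ± 0.21 between the responses. Ggnbp1 (-0.69) and Cep95 (-0.97) came next among lower genes, and Macroh2a2 (1.18) and Ror1 (1.24) had the smallest p among higher ones. The count was 481 without Mcm8Ko_PBS replicate 2 and 1 without Mcm8Ko_LCWE replicate 4. It was 2235 among libraries numbered 100 to under 200, where the knockout PBS group is 1 library assumed to vary like the others, and 0 with the range as a covariate.

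**Figure D3:**
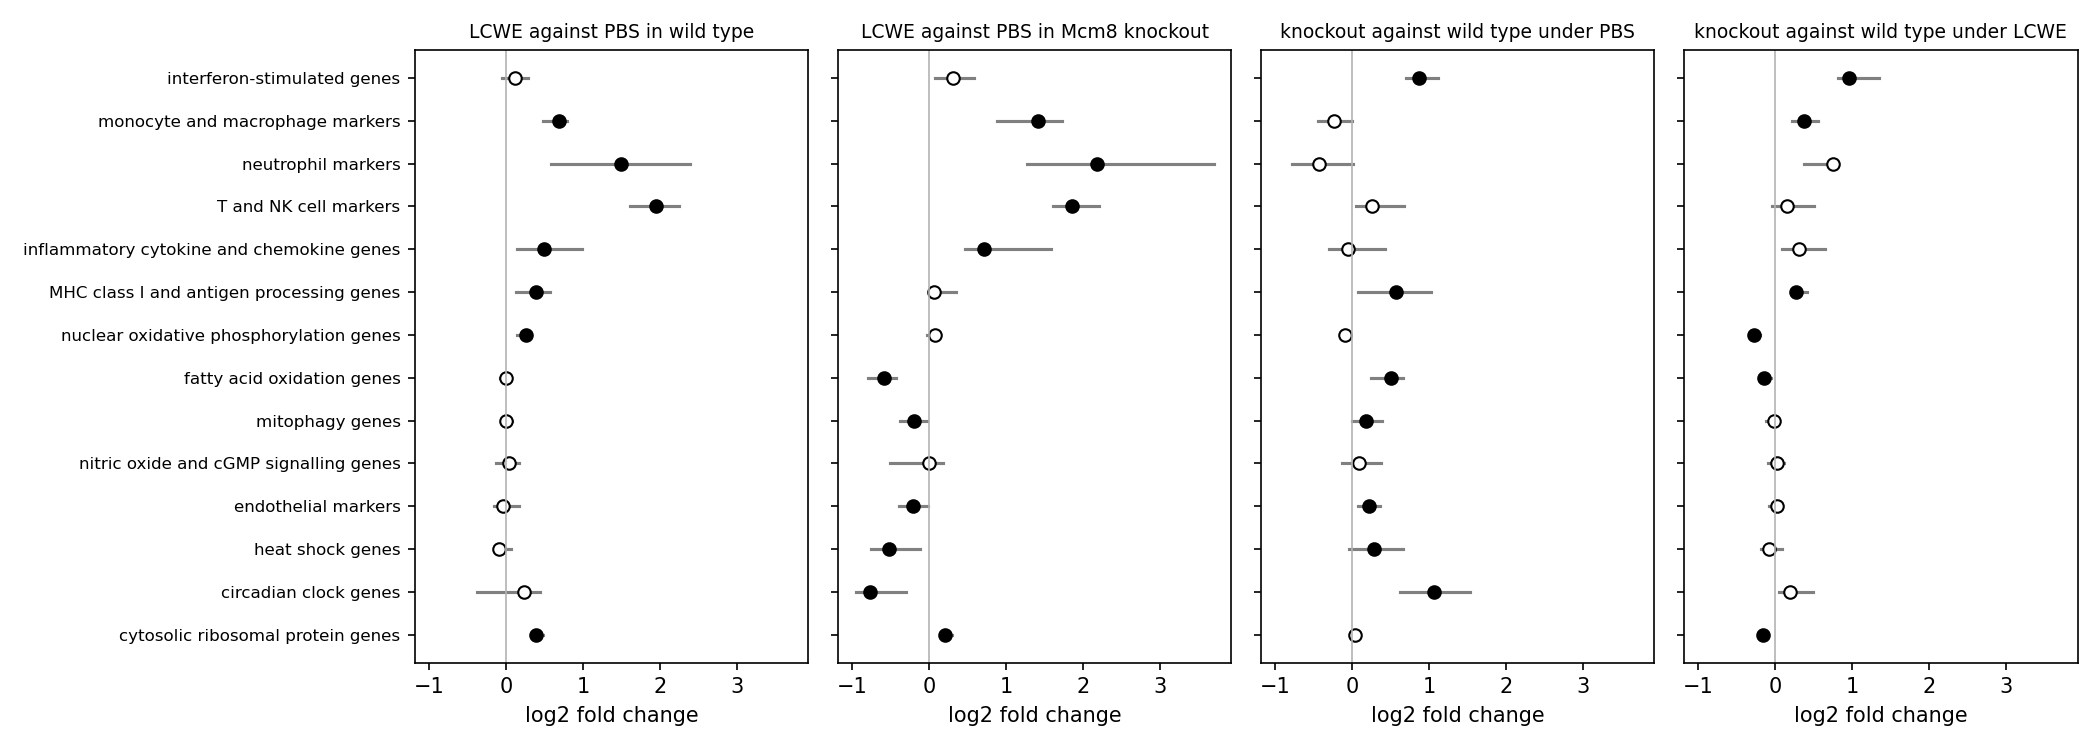
Median log2 fold change (points) and range from the first to the third quartile of the members (lines) of 14 gene lists in 4 comparisons. Filled points passed the camera test with its preset correlation. The interferon-stimulated genes lie at 0.86 and 0.95 in the knockout against wild type under PBS and LCWE, and at 0.11 and 0.31 in LCWE against PBS.

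The series names mitophagy and nitric oxide signalling, and both lists were tested in each comparison. Mitophagy genes had a median of -0.20 after LCWE in the knockout, with 1 of 30 lower over all genes and 4 adjusted over the list alone. Camera gave the mitophagy list an adjusted p = 0.00327 (adjusted p = 0.485 with an estimated correlation). It was not called without Mcm8Ko_PBS replicate 1 and Mcm8Ko_LCWE replicate 2 (camera adjusted p = 0.174), among libraries with Xist reads (0.823) or under 100 (0.709, higher). The called gene was Bnip3, a mitophagy receptor of the outer mitochondrial membrane, at 257 ± 166 CPM after PBS (n = 3) and 105 ± 32.6 CPM after LCWE (n = 5). It fell by 1.38 (edgeR adjusted p = 0.0304), and differed by 0.0356 within libraries numbered under 100, with a lone PBS library. Under PBS the list had a median of 0.18 in the knockout, with 0 of 30 called over all genes, 6 higher adjusted over the list alone and Bnip3 at 1.23 ± 0.30 (adjusted p = 0.0561). Camera gave the mitophagy list an adjusted p = 0.00599 (adjusted p = 0.577 with an estimated correlation). The responses to LCWE differed by a median of -0.22. Camera gave the mitophagy list an adjusted p = 0.000182 (adjusted p = 0.413 with an estimated correlation). That call was also lost without Mcm8Ko_PBS replicate 1 and Mcm8Ko_LCWE replicate 2 (0.0727) and among libraries with Xist reads (0.662). The list was not called after LCWE in wild type (camera adjusted p = 0.552) or between genotypes under LCWE (camera adjusted p = 0.202). The mitophagy kinase gene Pink1 was not called in any comparison, at -0.44 ± 0.18 after LCWE in the knockout and 0.20 ± 0.18 in the knockout under PBS.

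Nitric oxide and cGMP signalling genes were not called as a list in any of the 5 tests, with medians from -0.08 to 0.09 and camera adjusted p from 0.489 upward. The endothelial synthase gene Nos3 lay at 105 ± 11.1 CPM in wild-type PBS hearts (n = 5). It differed by -0.04 ± 0.14 and -0.29 ± 0.17 after LCWE in wild type and knockout, and by 0.27 ± 0.17 and 0.02 ± 0.14 in the knockout under PBS and LCWE. The inducible synthase gene Nos2 lay at 26.1 ± 3.93 CPM in wild-type PBS, 15.1 ± 9.09 in knockout PBS, 23.9 ± 5.79 in wild-type LCWE and 23.1 ± 6.19 in knockout LCWE hearts (n = 5, 3, 6 and 5), and neither gene was called. The natriuretic peptide gene Nppb, a marker of cardiac stress, differed by 0.76 ± 0.33 after LCWE in wild type and 1.47 ± 0.42 in the knockout (edgeR adjusted p = 0.772 and 0.0580). Nppa differed by -0.09 ± 0.34 and 0.44 ± 0.41, and the interleukin gene Il1b by -0.11 ± 0.62 and 1.45 ± 0.77. The DNA sensing genes Cgas (0.42 ± 0.32 under PBS, 0.42 ± 0.27 under LCWE) and Sting1 (-0.34 ± 0.28 and 0.05 ± 0.23) were not called between genotypes, and Il6 did not pass the filter on low counts.

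Across genes, which are not independent replicates, the LCWE responses of the genotypes had a Pearson correlation of 0.384 (Spearman 0.407). The knockout effects under PBS and under LCWE had a correlation of 0.273 (Spearman 0.30). The knockout effect under PBS and the LCWE response in the knockout had a correlation of -0.700 (Spearman -0.771, covariance -0.179), and both use the same 3 knockout PBS libraries. Of the genes higher in the knockout under PBS, 61 were lower after LCWE in the knockout, among them Cyp4b1, Hspa1b and Sox17, against 1.56 for independent lists. Of those lower, 7, such as Macroh2a2, were higher, against 0.0900. In 20 simulations of unchanged groups with shared controls the median correlation was -0.638 (from -0.673 to -0.574) and the median covariance -0.0986. Their mean overlap was 0, but without effects hardly any gene is due to be called, so it sets no expectation for the overlap. The values of 1.56 and 0.0900 hold only for lists that share no libraries. The 3 libraries cannot be divided into parts of at least 2, so part of the excess may come from the shared controls.

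Transcripts of other tissues also differed between libraries. Alb, the serum albumin gene of the liver, was over 20 CPM in 13 libraries (73.0 to 348 CPM) and at 3.22 CPM or less in the other 6. The skeletal muscle myosin gene Myh4 was over 20 CPM in 14 libraries (75.9 to 144 CPM) and at 2.87 CPM or less in the other 5. The intestinal lysozyme gene Lyz1 was over 10 CPM in 6 libraries. Alb was over 20 CPM in 2 of 5 wild-type PBS, 2 of 3 knockout PBS, 4 of 6 wild-type LCWE and 5 of 5 knockout LCWE libraries. Y-linked genes held 1754 to 2164 counts in 0 of 5, 1 of 3, 1 of 6 and 3 of 5 libraries in the same order and at most 37 counts in the others, and the labels give no sex. Myh7, the slow myosin heavy chain gene that rises under cardiac load, lay between 12907 and 20549.8 CPM in Mcm8Ko_PBS replicates 1 and 3 and Mcm8Ko_LCWE replicates 4 and 5. In the other 15 libraries it lay between 458 and 3273 CPM. It was not called between genotypes under PBS (2.62 ± 1.08, edgeR adjusted p = 0.197) or LCWE (2.20 ± 0.93, adjusted p = 0.861).

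**Figure D4:**
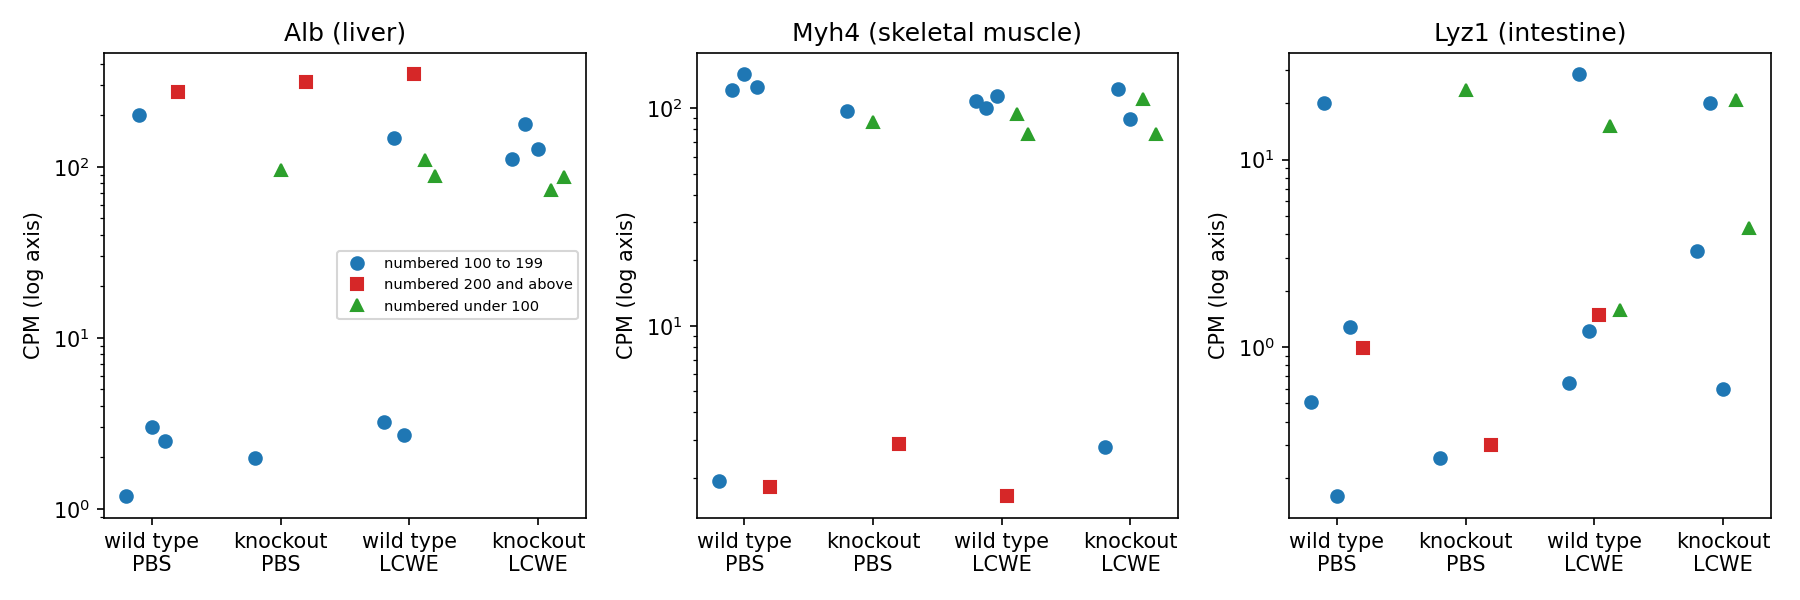
CPM (log axis) of Alb, Myh4 and Lyz1 in each of the 19 libraries, by group, with the marker showing the range of the sample number. Alb lies between 73.0 and 348 CPM in 13 libraries and at 3.22 CPM or less in the other 6.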

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

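In this part the test of genotype on the interferon list, the requirement that a bound be passed by more than its standard error, part of the genes given to Dixon's test, the tests of other tissues by genotype or treatment, and the sample-number splits within 100 to under 200 were chosen after the results were seen, and the other tests before.

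Some libraries lay far from the others of their group by Dixon's test, which was run on 405 sets of values, those of each gene given a value in the results, some further genes and 3 library measures in each of the 3 groups of 5 or 6 libraries. It picked 28 values, and chance picks about 1 in 20 groups, so about 20.2 would be picked with no cause. Values are in CPM, each against the median of the others in its group. Mcm8Ko_LCWE replicate 1 was the lowest of its group for Myh4 (2.77 against 99.9). Mcm8Ko_LCWE replicate 2 was the highest of its group for Hspa1a (8.77 against 3.05). Mcm8Ko_LCWE replicate 4 was the highest of its group for Cyp4b1 (42.7 against 30.0), Xist (208 against 0.821) and Eif2s3x (83.7 against 50.3). Mcm8Ko_LCWE replicate 5 was the highest of its group for Ciart (26.1 against 2.84). Wt_LCWE replicate 1 was the lowest of its group for Xist (1.001 against 193). Wt_LCWE replicate 3 was the highest of its group for Fahd1 (113 against 83.4). Wt_LCWE replicate 3 was the lowest of its group for Tsc22d3 (54.9 against 89.5), Hspa1a (1.06 against 2.76), Rasgrp2 (43.6 against 63.1) and Neat1 (1241 against 1932). Wt_LCWE replicate 4 was the lowest of its group for Myh4 (1.64 against 101). Wt_LCWE replicate 5 was the highest of its group for Uros (32.7 against 29.5) and Myl7 (7.36 against 0.557). Wt_LCWE replicate 6 was the highest of its group for Ciart (17.4 against 2.003). Wt_PBS replicate 2 was the highest of its group for Il17rd (15.95 against 12.6) and Lyz1 (20.1 against 0.744). Wt_PBS replicate 3 was the highest of its group for Cmtm8 (19.9 against 16.2). Wt_PBS replicate 4 was the lowest of its group for Nos3 (86.2 against 109.8), Isg15 (1.96 against 7.96), Ifit3 (3.44 against 17.8), Stat2 (20.7 against 39.8), Irf7 (5.94 against 27.3), Ifit1 (2.03 against 9.03) and Mx1 (0.0675 against 1.07). Wt_PBS replicate 5 was the highest of its group for Als2cl (91.6 against 74.1). Wt_PBS replicate 5 was the lowest of its group for Gas7 (11.9 against 17.7).

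The LCWE responses of the genotypes differed in 14 gene lists by the interaction test with a preset correlation, none of which was called with an estimated correlation (smallest adjusted p = 0.413). The median log2 differences, knockout response minus wild-type response, were as follows: fatty acid oxidation genes (-0.61), erythroid and platelet markers (-1.54), heat shock genes (-0.37), mitophagy genes (-0.22), oxidative stress response genes (-0.30), nuclear oxidative phosphorylation genes (-0.17), circadian clock genes (-0.92), monocyte and macrophage markers (0.65), endothelial markers (-0.27), fibroblast and extracellular matrix genes (0.63), cell cycle genes (0.30), Schwann and neuronal markers (0.45), mitochondrial DNA maintenance and biogenesis genes (-0.16), autophagy core and lysosome genes (-0.0525).

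Chance cannot be excluded for the count of genes after LCWE in the knockout (415 genes, highest other split 902, as many in 4 of 56 splits) or between genotypes under LCWE (1 gene, highest other 440, 7 of 100). That gene was Mcm8, for which the exact permutation p was 0.00216. The real split gave the most genes for the knockout under PBS (86 genes, highest other 26, 1 of 56 splits). It also did so for LCWE in wild type among libraries numbered 100 to under 200 (1247 genes, highest other 1, 1 of 35). These are the smallest shares such splits can give, they were not adjusted over the contrasts, and that range was chosen after the data were seen. The counts became 0 without Wt_PBS replicate 1 and 6 without Wt_LCWE replicate 2, so chance is not excluded for them. Where 0 genes were called, after LCWE in wild type over all libraries (highest other 246) and in the interaction (highest other 122), each of the 100 splits has as many by definition, so these counts decide nothing about chance. The splits with 246 and 440 genes each differ by 1 library from the division into numbers 100 to under 200 and others, which points to a structure of the samples. The split with 902 genes exchanged Mcm8Ko_PBS replicate 2 and Mcm8Ko_LCWE replicate 4, both numbered under 100, so the number ranges do not account for it.

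Transcripts of liver, skeletal muscle and intestine were present in part of the hearts. The 7 liver genes not examined before (Apoa2, Apoc3, Cyp2e1, Ahsg, Hpx, Ambp and Ttr) followed Alb across the 19 libraries with a median Spearman correlation of 0.947 (0.911 to 0.964), as reads from another tissue would, and Alb reached 348 CPM. A difference by genotype or treatment was not excluded, with a smallest adjusted exact permutation p of 0.688 over 6 tests. Whether the reads came from tissue, from blood or from library preparation may not be decided from these tables.

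Of the genes called in the knockout under PBS, 86 of 86 kept their direction without Mcm8Ko_PBS replicate 1, the library of this group with Y-linked reads (2164 counts), but 0 were called. Their median absolute log2 fold went from 0.99 to 0.74, and the median standard error of a gene from 0.210 to 0.211. The median gene kept 76.0% of its change. The standard error of a gene was 21.3% of the fold of 0.99, which is not the error of the percent kept. But 0 genes were called without Wt_PBS replicate 1 as well, where 99.9% of the fold was kept. A smaller fold is therefore not shown to be why the calls ended. With Xist and Y-linked levels as covariates the median gene kept 89.7%, and again 0 genes were called. The median fold was then 0.89 and the median standard error of a gene 0.211, again 21.3% of the fold of 0.99. The 3 knockout libraries lay 1.32, 0.35 and 0.98 from the wild-type mean in the direction of the calls (median over genes, replicates 1, 2 and 3). A single library and a sex difference cannot be told apart from loss of Mcm8 here. Both shares lie within that standard error of a gene from the 75% set as the bound, and the error of the shares themselves was not computed. Genotype is a candidate explanation that stays open.

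The interferon list lay higher in knockout hearts. With Xist and Y-linked levels as covariates the median kept 119% (SE 42.7) of its value. With the macrophage level it kept 88.6% (SE 32.4) and with the sample-number range 89.9% (SE 34.7). These 2 stay open because the standard error reaches below the bound of 75%. Sex stays open too, as 119% passes it by barely 1 SE. Xist reads occurred in 1 of 5 knockout and 5 of 6 wild-type LCWE libraries, so sex overlapped genotype. Each SE is that of the list's mean difference in the fit with the covariate, as a percent of the difference without it. Permuting genotype within each treatment gave an exact p = 0.00309 for the mean level of the list over 25872 assignments (difference 0.99 under LCWE, exact p = 0.0238, and 0.82 under PBS, exact p = 0.107). An effect of genotype is therefore a hypothesis, and adjusted p = 0.392 with an estimated correlation limits it.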

How the results depend on the processing

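Fits with Xist and Y-linked levels, with other tissues as covariates, of libraries with Xist reads, of 1 number range and without 2 libraries were chosen after the data were seen. Genes called for LCWE in wild type were 0, with 1 by DESeq2, 1 by limma-voom with library weights and 1247 among libraries numbered 100 to under 200. For LCWE in the knockout the 415 genes became 229 with library totals alone (42.4% higher, against 28.2%), 1253 by DESeq2, 113 by limma-voom, 1415 with library weights, 0 with only the groups compared, 116 with the number range, 877 with the Y-linked level, 16 with genes detected, 1363 with Xist and Y-linked levels, 0 among libraries with Xist reads, 3941 among numbers 100 to under 200, 3 under 100, 127 with other tissues (48.8% higher) and 10 without Mcm8Ko_PBS replicate 1 and Mcm8Ko_LCWE replicate 2. For the knockout under PBS the 86 genes became, in the same order, 21 (76.2% higher, against 87.2%), 701, 1, 749, 1, 524, 0, 206, 0, 1, 3936, none computed under 100, 1 and 2, and 57 with 1 surrogate variable. For the knockout under LCWE the single gene became 6 by DESeq2, 2 with library weights, 0 under the stricter filter, which left Mcm8 untested, 18 with Xist reads, 0 among 100 to under 200, 128 under 100 and 2 without the 2 libraries. The interaction gave 3 by DESeq2, 21 with library weights and 2235 among 100 to under 200, and library totals alone moved the median of all genes by 0.118 there. Where a group was left with 1 library (knockout PBS in each number range, knockout LCWE among those with Xist reads), it was assumed to vary like the others. Mcm8 stayed lower in every fit, but lost its call under PBS by limma-voom (-2.23, adjusted p = 0.0753), with only the groups compared (-2.27, adjusted p = 0.0839), with the Y-linked level (-2.36, adjusted p = 0.0569), with Xist and Y-linked levels (-2.26, adjusted p = 0.109), among libraries with Xist reads (-2.41, adjusted p = 0.0830) and without the 2 libraries (-2.41, adjusted p = 0.0921), and under LCWE among 100 to under 200 (-3.24, adjusted p = 0.182). With library weights the correlation of LCWE responses was 0.103 and of knockout effects 0.0720, and the latter was -0.0133 among 100 to under 200. With an estimated correlation 0 lists were called in each of the 5 tests, and fry called 0, 4, 0, 0 and 0. The number range left 9 lists for LCWE in wild type. For the knockout under LCWE, 21 lists were called with the Y-linked level, 7 with genes detected, 19 with Xist and Y-linked levels and 20 with Xist reads, and for the interaction 7 without the 2 libraries. Leaving out 1 library gave, in the order of the contrasts, 0 to 0, 1 to 2935, 0 to 2606, 1 to 2 and 0 to 481 genes, 11 to 17, 13 to 21, 11 to 18, 10 to 18 and 9 to 21 lists, Mcm8 at -2.41 to -2.13 under PBS and -3.71 to -3.12 under LCWE, and correlations of 0.267 to 0.421 and 0.182 to 0.308. After LCWE in the knockout, Bnip3 (0.0356) and Myh7 (4.53) turned under 100. Of all named genes over all fits, 12714 values kept direction and side of the threshold, 914 lost it, 426 gained it, 485 uncalled values moved beyond their spread and 2 turned. The cause of these changes was not tested. After LCWE in wild type, list calls were lost with the Y-linked level (MCM and recombination, cell cycle), with genes detected (smooth muscle, MCM and recombination, cell cycle), and with Xist and Y-linked levels (MCM and recombination, cell cycle). They were also lost with other tissues (MCM and recombination), among libraries with Xist reads (MCM and recombination, cell cycle), and among 100 to under 200 (complement, smooth muscle, lymphocyte progenitor, MCM and recombination). After LCWE in the knockout, list calls were lost with the Y-linked level (extracellular matrix, MCM and recombination, unfolded protein response), with Xist and Y-linked levels (extracellular matrix, unfolded protein response), and among libraries with Xist reads (extracellular matrix, mitophagy, fatty acid oxidation, MCM and recombination, unfolded protein response, clock). They were also lost among 100 to under 200 (neutrophil, inflammasome, endothelial, MCM and recombination, unfolded protein response, heat shock, ribosomal protein), under 100 (mitophagy, fatty acid oxidation, MCM and recombination, cell cycle, unfolded protein response, clock), and without the 2 libraries (inflammasome, cytokine, mitophagy, clock). For the knockout under PBS, list calls were lost with genes detected (DNA sensing), with Xist and Y-linked levels (MHC class II), and among libraries with Xist reads (MHC class II). They were also lost among 100 to under 200 (MHC class I, DNA sensing, complement, platelet and erythroid, MCM and recombination, unfolded protein response, heat shock) and without the 2 libraries (MHC class II). For the knockout under LCWE, list calls were lost with the Y-linked level (immediate early), with genes detected (macrophage, complement, contractile, mitochondrial DNA, immediate early), with Xist and Y-linked levels (platelet and erythroid, immediate early, ribosomal protein), and with other tissues (contractile, ribosomal protein). They were also lost among libraries with Xist reads (platelet and erythroid, mitochondrial DNA, immediate early), among 100 to under 200 (MHC class I, DNA sensing, complement, contractile, mitochondrial DNA, fatty acid oxidation, immediate early), under 100 (platelet and erythroid, fatty acid oxidation), and without the 2 libraries (contractile, fatty acid oxidation, immediate early, ribosomal protein). For the interaction, list calls were lost with genes detected (autophagy, mitochondrial DNA), with other tissues (autophagy), and among libraries with Xist reads (extracellular matrix, platelet and erythroid, mitophagy, autophagy, mitochondrial DNA, fatty acid oxidation, oxidative stress response, clock). They were also lost among 100 to under 200 (macrophage, endothelial, Schwann and neuronal, mitochondrial DNA, cell cycle, heat shock) and without the 2 libraries (extracellular matrix, Schwann and neuronal, mitophagy, autophagy, oxidative phosphorylation, mitochondrial DNA, cell cycle, clock). No paired analysis was made because the labels state no pairs. Beside the number ranges, neighbouring sample numbers were not used as blocks, so any difference between such sets stays in the spread. Depth ranged from 11853233 to 16145911 counts, so low genes such as Mcm8 limit precision in the knockout.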

Other observations

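Between the 11 libraries numbered 100 to under 200 and the others, with the 4 groups in the model, the smallest p belonged to the NAD hydrolase gene Cd38 (0.88 ± 0.09) and the elastic fibre gene Mfap2 (1.20 ± 0.12), both higher in that range. Other called genes were picked by hand after their values were seen, and no gene list was tested for this comparison. Of these the elastin gene Eln (1.47 ± 0.24), the matrix glycoprotein gene Sparc (1.29 ± 0.21), the fibrillar collagen gene Col5a2 (0.77 ± 0.12) and the matrix protease genes Mmp2 (0.73 ± 0.13) and Mmp14 (0.69 ± 0.10) were higher. The calcium channel gene Cacna1s (-1.45 ± 0.24), the fatty acyl-CoA ligase gene Acsl6 (-1.26 ± 0.20) and the nuclear RNA Neat1 (-0.59 ± 0.11) were lower.

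The atrial light chain gene Myl7 lay at 86.6 CPM in Mcm8Ko_LCWE replicate 2, 41.0 CPM in Mcm8Ko_LCWE replicate 4, 29.0 CPM in Mcm8Ko_PBS replicate 2 and 7.36 CPM in Wt_LCWE replicate 5, and at 1.22 CPM or less in the other 15 libraries.

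Among the tests in this part, those of the sample-number range, of Myh7 by genotype and of glucocorticoid-induced genes were chosen after the result was seen, and those of the X chromosome and of the genes near Mcm8 before.

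A division of the samples by number was tested as a hypothesis, because other splits had called more genes than the real ones. Between the 11 libraries numbered 100 to under 200 and the other 8, edgeR called 667 genes (347 higher, 320 lower; 3063 at an unadjusted p under 0.05). Of 100 assignments within groups, 1, the real one, gave as many, and the highest other gave 9. The numbers may mark a batch, an age or a cohort, which the labels do not state.

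In Mcm8Ko_LCWE replicate 2, which held 10 Xist and 25 Y-linked counts, 6 X-linked genes that escape inactivation (Kdm6a, Kdm5c, Eif2s3x, Ddx3x, Utp14a and Pbdc1) had a mean of 4.92 log2 CPM. This was -0.36 from the lowest of the 13 libraries with 2351 to 3647 Xist counts (mean 5.41 ± 0.08), and near the 5 libraries with 1754 to 2164 Y-linked counts (4.98 ± 0.13). The value is consistent with a single X chromosome, as a hypothesis on 1 library.

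Levels of Myh7 over 10000 CPM occurred in 4 libraries, all knockout. Permuting genotype within treatments gave an exact p = 0.0550 for its log2 level (difference 2.14 under PBS and 1.15 under LCWE), so genotype stays open.

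Genes within 10 Mb of Mcm8, which could differ if DNA of another strain flanked the deleted gene, had p under 0.05 between genotypes in 25% of 116 genes under PBS against 19.7% of other genes (Fisher's exact p = 0.160), and in 6.90% against 5.51% under LCWE (Fisher's exact p = 0.536). Flanking DNA cannot be told apart from its absence with these shares, since both odds ratios were above 1 (1.36 and 1.27).

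The clock genes Per2, Ciart and Dbp were compared with 12 genes that glucocorticoids induce, since stress hormones could move both. Across the 19 libraries their means had a Pearson correlation of 0.320 (permutation p = 0.181) and a Spearman correlation of 0.265 (permutation p = 0.271). It was 1 relation of this kind, so no adjustment applied, and without the 2 libraries farthest from the median (Mcm8Ko_PBS replicate 1 and Wt_LCWE replicate 3) the Pearson value was 0.0443. The relation was not shown and is not excluded.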
